A study of Emblica officinalis and Allium sativum and Glycine max with 8 samples.

How the data were processed

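Small RNA libraries were sequenced from exosome-like nanovesicles of amla, garlic, soybean and turmeric, 2 libraries per plant, 8 in all. Per the labels' protocols, the edible parts were ground in buffered saline, cleared by centrifugation, and the vesicles were precipitated with polyethylene glycol before RNA extraction, soybeans being soaked overnight first. Per the design text, the 2 libraries of a plant came from produce of different sources, which it names biological replicates, and RNA was taken from independent vesicle batches. Plants were taken from the sample titles, and the organism labels named the same plants. The design and protocol texts name ginger and not garlic, so that the identity of the libraries labelled garlic rests on the titles and organism labels.

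The authors deposited a table of whole-number counts per miRNA name and a table of normalized values. The counts are raw as far as their header and whole-number values show, and the aligner, the miRNA reference and the adapter handling are not given in the sources used here. No count between 1 and 4 occurs in it, the lowest count above 0 being 5, as a minimum applied before deposit would leave; no label records such a step. The deposited normalized values, treated as a signal with no fixed total, equal in every library the count multiplied by 1 factor, with a relative range of at most 8.6e-15 across names. That factor is the CPM scale of the library total times the edgeR TMM factor computed on all names, as found from the values. All columns of both tables were matched to samples by title. The 896 names carry no species prefix and no sequence, so a name in animal style says which catalogue entry the authors' counting assigned, not which organism the RNA came from. Nor could any name, in plant style or not, be checked against fragments of ribosomal or transfer RNA. Of the 896 names, 344 had the same counts in all libraries as an earlier name, which includes names rarely above 0, and 4 of these were among the tested names; 2 names repeated another in a different letter case.

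Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Names were kept by filterByExpr with a minimum count of 10 by plant, which left 316 names with 94.7% to 99.5% of each library's counts, 56 of them in plant style. TMM factors were computed on the kept names and ranged from 0.548 to 2.93. The quasi-likelihood model had 1 term per plant and no covariate, all 8 libraries sharing 1 estimate of the spread (common dispersion 0.877, 4 residual degrees of freedom, prior degrees of freedom 1.87). Each plant was compared with the mean of the 3 other plants on the log scale, and all 6 pairs of plants were compared. Tests were two-sided, with Benjamini-Hochberg adjustment over the 316 names and a threshold of 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. Because the mean of the others is taken on the log scale, a plant at 0 lowers it strongly. Where any library on either side was at 0, the fold of a called name is given as a lower bound and not as fitted. For the bound, 5 counts, the lowest count above 0 in the table, were put in for each library at 0 on the lower side, and the higher side was taken as counted. A floor of 5 counts corresponds to 101 CPM in amla, 72.9 in garlic, 72.8 in soybean and 76.9 in turmeric after TMM scaling. Each bound allows for the counts at 0 only, holds under TMM scaling and can be lower under another scaling. No single name can be separated at the threshold by an exact two-sided rank test of 2 against 6 libraries, whose smallest p is 0.0714, so that all calls rest on the spread shared across names.

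The names given in the text followed a rule. For each plant these were the 10 highest and the 5 lowest by log2 fold change among names past the threshold whose 2 libraries lay above or below all 6 others, and the 10 most abundant names. For each pair of plants the 3 largest changes each way were added where not yet named, and identical rows counted as 1. Names outside this rule are marked in the text as given after their values were seen, or appear as members of a list. Family sums added all names with the same number, hyphenated and plant-style numbers kept apart, and 296 families were tested in the same way. Of 8 lists of families fixed beforehand, the 4 with at least 3 tested names (development regulators, defence, legume and let-7 names as animal markers) were tested with limma camera at a preset correlation of 0.01, adjusted over 16 combinations of list and plant. Auxin, nutrient, small RNA pathway and monocot lists are given as shares. A wider list of animal names with hyphens was added after the data were seen, because no name carried a species prefix. Detection, shares, Wilson intervals at 95% and correlations across names were computed in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Intervals cover counting error only, since PCR copies are not independent molecules. A floor stands in for a count at 0 and does not cover counting error. Any bound, and most of all a small one such as that of miR-24 in amla, can thus lie above the true fold.

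The alternatives were DESeq2 1.42.0 size factors in the edgeR fit, total-count scaling, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, identical names merged, each library left out in turn, other detection limits, libraries thinned to the smallest total, an estimated correlation or fry for lists, and the authors' normalized values for composition. Scaling on plant-style names alone was added after the data were seen. Without the filter the spread was shared over all 896 names, sparse ones included. Very small p from that fit are thus no measure of how the libraries of 1 plant varied. The rule, the lists, the tests and the other alternatives were set before the data were examined. The 2 libraries of each plant differed beyond counting error, with a chi-square per degree of freedom of 14.4 in amla, 24.3 in garlic, 143 in soybean and 54.3 in turmeric, and each library was counted as 1 replicate. A second preparation of the same RNA could also differ by this much.

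The edgeR test was run on simulated data with 200 of 896 names changed at the real library sizes. At a dispersion of 0.2 it recovered 85.2% of changes of log2 3 and 83.1% of log2 6 in amla, 80.3% and 92.9% in garlic, 81.9% and 92.8% in soybean, and 71.8% and 95.6% in turmeric, among 329, 303, 306 and 326 tested names, and it called 3 of 159 unchanged names in amla, 5 of 142 in garlic, 2 of 151 in soybean and 9 of 151 in turmeric. At the dispersion of the real data it recovered 15% and 65.2% in amla, 18.9% and 64.1% in garlic, 20% and 67.9% in soybean, and 13.4% and 74.1% in turmeric, among 346, 356, 316 and 314 tested names, and called 1 of 177 unchanged names in amla, 0 of 174 in garlic, 0 of 152 in soybean and 0 of 151 in turmeric. A difference that did not pass here is thus not shown to be absent. In the simulation unchanged names had the same mean in all plants, and as many names were raised as lowered. It thus did not test the scaling where most changes go 1 way, nor names set to 0 in whole plants, as in the real data. Names of nearly identical sequence, such as let-7f, let-7g and let-7i, miR-148a and miR-148d, or miR482 and miR482h, can share or trade reads, and their separate values are uncertain. In 4 of 57 cases of a family with at least 20 counts in both libraries of a plant, these libraries had no member name in common.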

Results

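Small RNA was sequenced from exosome-like nanovesicles, the small membrane vesicles that can be precipitated from plant extracts, of 4 edible plants. The plants were amla (Indian gooseberry, Emblica officinalis), garlic (Allium sativum), soybean (Glycine max) and turmeric (Curcuma longa), with 2 libraries per plant made from produce of different market sources. The study asked which microRNAs (miRNAs), short RNAs that silence matching messenger RNAs, were enriched in the vesicles of each plant. The design text named ginger where the titles and organism labels named garlic, and the libraries labelled garlic are called garlic here. Total counts were 52135 and 45324 in amla, 86029 and 123730 in garlic, 26961 and 71315 in soybean, and 94707 and 105090 in turmeric. The count table listed 896 miRNA names, of which 134 to 450 were above 0 in a library, and the lowest count above 0 was 5. Of these names, 197 were in the style of plant entries, without a hyphen (miR159), and 699 were in the hyphenated style of animal and viral entries (miR-6808), and no name carried a species prefix.

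Amla and turmeric vesicles were dominated by 1 name, miR-6808, an entry of the human miRNA catalogue, whereas garlic and soybean vesicles had no such single name. miR-6808 took 56.3% ± 1.88 (SD, n = 2) of the counts in amla and 69.8% ± 0.197 (SD, n = 2) in turmeric. In garlic it took 1.33% and 1.34% of counts and in soybean 0.612% and 0.296%. The most abundant names in garlic were miR-8546 with 16.7% ± 0.372 and miR2916, an entry first described in poplar, with 15.2% ± 0.484 (SD, n = 2). Soybean was led by miR-1806, with 29.8% of counts in soybean 1 (95% Wilson interval 29.2% to 30.3%) and 11.2% in soybean 2 (11% to 11.4%), and by miR159, a regulator of MYB transcription factors, with 18.4% ± 2.88 (SD, n = 2). miR159 took 5.22% ± 0.213 of the counts in amla, 5.60% ± 0.694 in garlic and 2.91% ± 0.676 in turmeric (SD, n = 2). miR156, which targets SPL transcription factors, took 4.62% ± 0.0368 in amla and 2.86% ± 0.727 in turmeric (SD, n = 2). The 10 most abundant names together held 85.0% ± 0.788 of counts in amla, 70.3% ± 0.335 in garlic, 70.0% ± 11.6 in soybean and 89.9% ± 1.30 in turmeric (SD, n = 2). Names in plant style held 20.4% ± 2.77 of counts in amla, 44.0% ± 0.489 in garlic, 39.2% ± 3.92 in soybean and 11.2% ± 0.424 in turmeric (SD, n = 2).

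**Figure D1:**
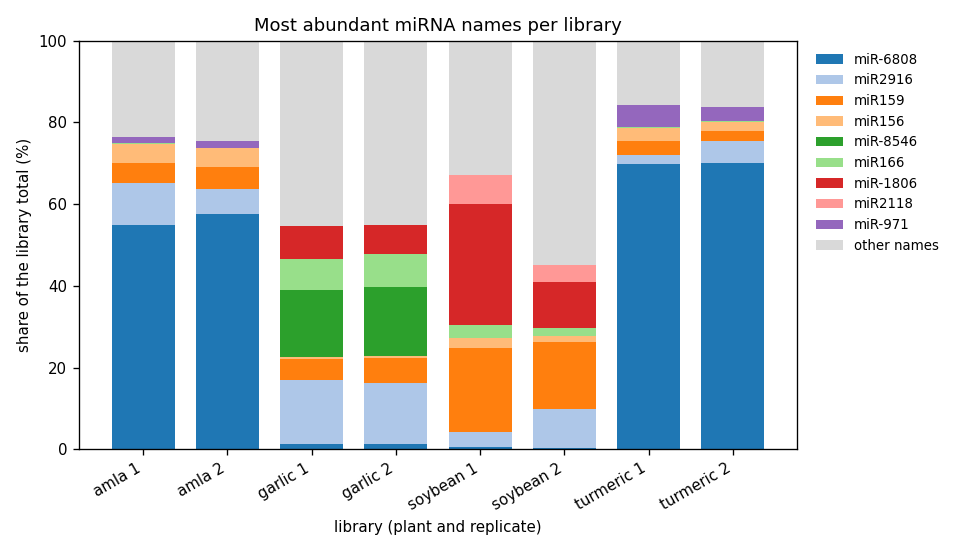
Stacked bars give the share of counts (percent of the library total) of 9 abundant miRNA names and of all other names in each of the 8 libraries. miR-6808 takes 56.3% of counts in amla and 69.8% in turmeric on average.

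The plant-style names miR2916, miR159, miR156, miR396, miR167 and miR3630 were detected in the vesicles of all 4 plants. Detection meant at least 10 counts in both libraries of a plant. miR396 targets GRF growth factors and miR167 targets the auxin response factors ARF6 and ARF8. In all, 25 names met this rule in every plant. Among the other 19 were miR-21, miR-143, miR-192, miR-126 and let-7, which are well known from animals; let-7 was listed in 2 spellings. Amla and turmeric each had 98 detected names, garlic 176 and soybean 72, and 23, 24, 131 and 34 of these were detected in that plant alone, in the order amla, turmeric, garlic and soybean. Amla and turmeric shared 66 of the 130 names detected in either, or 50.8%, while the other pairs of plants shared 13.2% to 25%. Across the 316 tested names, which are not independent replicates, the log2 abundance of the 2 libraries of a plant had a Pearson r of 0.841 in soybean, 0.845 in turmeric, 0.870 in amla and 0.940 in garlic. The 4 amla to turmeric values were 0.694, 0.715, 0.772 and 0.823, and all other pairs of libraries lay between -0.102 and 0.313. Detection moved with depth: after every library was thinned to the smallest total, garlic had 93 detected names, turmeric 50, and 14 were detected in all 4 plants. The names detected in 1 plant alone then numbered 24 in amla, 6 in turmeric, 63 in garlic and 35 in soybean.

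**Figure D2:**
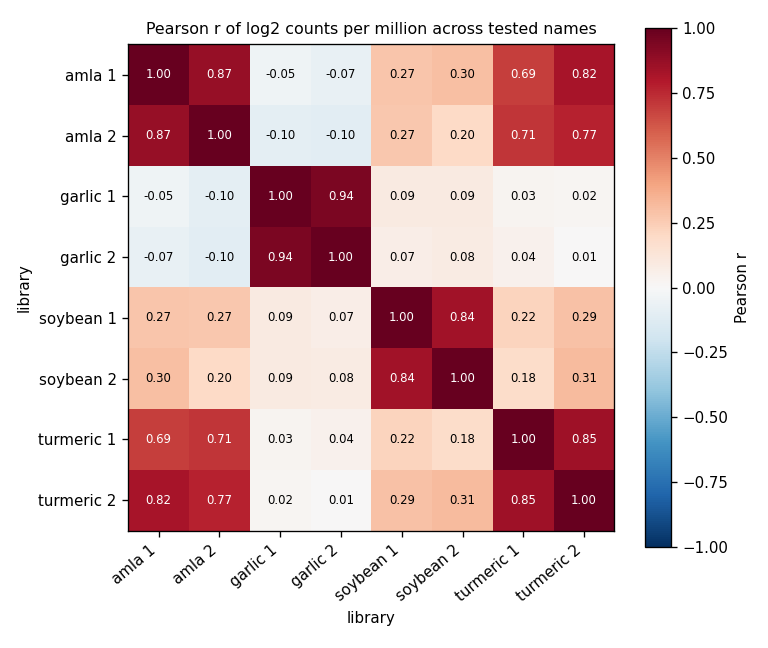
The heat map gives the Pearson r of log2 CPM across the 316 tested names for each pair of the 8 libraries. Amla and turmeric libraries have r of 0.694 to 0.823 with each other, and other pairs of different plants have at most 0.313.

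Amla vesicles carried more miR-6808, miR-93a, miR-10565, miR-6599 and 3 let-7 names than the mean of the other plants on the log scale. miR-6808 was 14.5-fold higher (log2 3.86 ± 0.49 SE, edgeR adjusted p = 0.0104, n = 2 amla and 6 other libraries). miR-93a (690 and 551 counts) was at least 29.2-fold higher and miR-10565 (2325 and 2019 counts) at least 74.2-fold higher. Both were also found in turmeric, miR-93a at 1056 and 807 counts and miR-10565 at 127 and 1322. The let-7 family controls developmental timing in animals. Its names let-7f (57 and 61 counts), let-7g (57 and 42) and let-7i (57 and 34) were at 0 in the 6 other libraries and at least 16.1-, 13.3- and 12.1-fold higher. The let-7 sequences are nearly identical and can share reads, and the summed let-7 family, with 233 and 198 counts in amla, was not called (log2 0.14 ± 0.33). In total edgeR called 58 names higher and 4 lower of 316, and 11 of the 58 were at 0 in all other libraries. Further higher names were miR-6599 (at least 47.7-fold), miR-8879 (at least 23.6-fold), miR5286b (at least 11.2-fold), miR-971, a fruit fly entry (at least 10.9-fold), miR-692 (at least 7.81-fold), miR-1301 (at least 7.48-fold) and miR-M26 (at least 4.10-fold). miR-971 had 776 and 745 counts in amla and more in turmeric (5215 and 3588), so its fold rests on garlic and soybean. Of the 4 lower names, miR12147 was at 0 in amla and at least 16-fold lower, and miR-1806, with 7 and 0 counts, was at least 129-fold lower (edgeR adjusted p = 0.0220). The others were miR-24 (at least 1.27-fold) and miR-9993a (at least 2.82-fold), the last named after its values were seen. Among the other abundant names, miR2916 (log2 0.11 ± 0.46), miR159 (log2 -0.50 ± 0.48), miR-143 (log2 0.47 ± 0.35), miR156 (log2 1.57 ± 0.46, edgeR adjusted p = 0.067) and miR-5365 (edgeR adjusted p = 0.187) did not pass. Without amla 1 edgeR called 0 names higher and 0 lower, with 65 and 7 at an unadjusted p under 0.05. Without amla 2 it again called 0 and 0, with 65 and 6 at an unadjusted p under 0.05. DESeq2 on all libraries called 37 higher and 13 lower, not including let-7f, let-7g, let-7i, miR5286b, miR-692, miR-1301 or miR-M26 (adjusted p of 0.119 to 0.308). Total-count scaling ended the calls of miR-10565 (edgeR adjusted p = 0.0501) and miR-24 (0.0560). Without garlic 1 or garlic 2 only 2 lower names were called, miR-24 (edgeR adjusted p = 0.116 and 0.123) and miR-9993a (0.0781 and 0.0908) being lost and miR-5365 passing (0.0157 and 0.0105). miR-9993a was also lost without soybean 2 (edgeR adjusted p = 0.9998) or turmeric 1 (0.0514) and with total-count (0.0534) or plant-style scaling (0.0556). miR-10565 was lost without soybean 2 (0.0635), turmeric 1 (0.0881) or turmeric 2 (0.0782), miR-1806 without turmeric 1 (0.0570) or turmeric 2 (0.0714), and miR156 passed without soybean 1 (0.0138) or soybean 2 (0.0497). miR156 also passed as higher with total-count scaling (edgeR adjusted p = 0.00931), plant-style scaling (0.00938) or no filter (0.0252), and miR-5365 with no filter (4.87e-13) or DESeq2 (adjusted p = 0.000508).

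Garlic vesicles had the most names of their own, led by miR-8546, miR-277, miR11072i and miR-7475, all at 0 in the 6 other libraries. miR-8546 had 14133 and 20977 counts and was at least 3122-fold higher than the mean of the other plants, and miR-277, a fruit fly entry, had 3612 and 5825 counts and was at least 841-fold higher (edgeR adjusted p = 0.00609 for both, n = 2 garlic and 6 other libraries). The plant-style miR11072i (3218 and 3256 counts) was at least 571-fold higher. miR166, which targets HD-ZIP III transcription factors, was at least 98.2-fold higher (edgeR adjusted p = 0.00609), and miR3630, an entry first described in grape, was 285-fold higher (log2 8.16 ± 0.49, edgeR adjusted p = 0.00116). edgeR called 129 names, of which 5 were lower and 96.1% higher. Of the higher names 91 were at 0 in all other libraries. In plant style, 33 names were higher and 3 lower. miR-7475 was at least 448-fold higher, miR-10570 256-fold, miR-3507 147-fold, miR-8120 130-fold, miR-6972 120-fold, miR-3620 113-fold and miR-9952c 105-fold, all as lower bounds. For miR-307 (731 and 1406 counts) the lower bound was log2 7.58. miR-1806 was at least 73.5-fold higher and miR2916 4.56-fold higher (log2 2.19 ± 0.43, edgeR adjusted p = 0.00712), and miR159 did not differ detectably (log2 0.54 ± 0.45). The share of miR-1806 was larger in soybean (29.8% and 11.2%) than in garlic (7.9% and 7.1%). Its fold rests on amla and turmeric, with 29 counts or fewer per library. Of the 5 lower names, miR162, which targets the processing enzyme DCL1, was at 0 in garlic and at least 14.5-fold lower, and miR482, a regulator of NBS-LRR resistance genes, was at least 29.1-fold lower. The related name miR482h had 119 and 173 counts in garlic and was at least 26-fold higher, and the summed miR482 family was not called (log2 0.12 ± 0.81). The remaining lower names, given after their values were seen, were miR-8117 (log2 -3.76 ± 0.81), miR-6808 (log2 -2.47 ± 0.63) and miR156 (log2 -1.93 ± 0.56, edgeR adjusted p = 0.0345). All 3 lost their calls without garlic 1 (edgeR adjusted p of 0.0697 to 0.145) or garlic 2 (0.0583 to 0.0934), miR-6808 and miR156 also without turmeric 1 (0.110 and 0.166) or turmeric 2 (0.120 and 0.132), and miR156 without amla 1 (0.0768). Tested among family sums, miR-6808 and miR156 did not pass in garlic (edgeR adjusted p = 0.0586 and 0.0791). DESeq2 called 59 names higher and 39 lower. edgeR called 38 higher and 2 lower without garlic 2, 2 lower without garlic 1, 9 lower without soybean 2 and 3 lower without turmeric 2. Of the names given by the fixed rule, miR2916 alone lost its call in edgeR fits with 1 library left out or another scaling, without garlic 2 (edgeR adjusted p = 0.0690), with total-count scaling (0.0893) and with scaling on plant-style names (0.485). miR482h was lost without garlic 2 (0.0544).

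Soybean vesicles stood out by miR2118 and miR-10286 and by the legume miRNA miR3522, none of which had a count under these names in the other plants. miR2118, which targets NBS-LRR resistance genes, had 1872 and 2856 counts and was at least 359-fold higher than the mean of the other plants (edgeR adjusted p = 0.0219, n = 2 soybean and 6 other libraries), and the miR2118 family had 5 counts in each garlic library. miR-10286 (1591 and 2547 counts) was at least 309-fold higher, miR-29b (461 and 433) at least 80.2-fold, and miR3522 (115 and 193) at least 22.6-fold. miR-148a, an entry known from animals, was at least 113-fold higher (edgeR adjusted p = 0.0235) but had 292 counts in soybean 1 and 3182 in soybean 2, and the near-identical miR-148d was at least 73.5-fold higher. edgeR called 25 names higher and 11 lower, with 16 of the 25 at 0 elsewhere. The other higher names were miR-1806 (at least 75.3-fold), miR-2571 (at least 34.2-fold), miR-9617 (at least 12.3-fold), miR-8457 (at least 11.8-fold), miR-9804 (at least 10.5-fold), miR-1662 (at least 8.70-fold) and miR-63 (at least 8.60-fold). miR-1806 was abundant in garlic too (6835 and 8802 counts), and its fold rests on amla and turmeric, with 29 counts or fewer per library. Names at 0 in soybean were lower by at least 116-fold for miR-971, 56.4-fold for miR-31, 43.2-fold for miR-7069, 23.4-fold for the poplar entry miR6478 and 22.3-fold for the moss entry miR1026, with edgeR adjusted p of 0.0115 to 0.0200. miR159 (log2 0.71 ± 0.45), miR2916 (log2 -1.81 ± 0.52), miR156 (log2 -1.15 ± 0.53), miR166 (edgeR adjusted p = 0.228) and miR-105 (edgeR adjusted p = 0.135) did not pass. DESeq2 called 25 names higher and 50 lower, not including miR-9617, miR-8457, miR-9804, miR-1662 or miR-63 (adjusted p of 0.0737 to 0.0970), and total-count scaling in edgeR 43 and 11. Without soybean 1 edgeR called 0 names higher, with 34 at an unadjusted p under 0.05. The higher count was 9 without amla 1, 11 without amla 2, 4 without garlic 1, 5 without garlic 2, and 1 without soybean 2, turmeric 1 or turmeric 2. The lower count was 3 without soybean 2 and 6 without turmeric 1 or turmeric 2. Each higher name given here lost its call in several of these fits (edgeR adjusted p up to 0.220), and tested among family sums miR-8457 (0.0587) and miR-63 (0.0757) did not pass. Of the lower names, miR-31 and miR6478 passed without any 1 library. The sum over all miR-31 names, with 0 and 30 counts in soybean, was called lower (edgeR adjusted p = 0.0383), but not with total-count scaling (0.144) or without any 1 of the amla, garlic or turmeric libraries (0.0749 to 0.163). miR-971 was lost without soybean 2 (0.102), turmeric 1 (0.0820) or turmeric 2 (0.0875), and miR-7069 (0.0670) and miR1026 (0.102) without soybean 2. miR166 passed as higher without amla 1 (0.0442) or with no filter (2.31e-05), and miR159 as higher with total-count scaling (0.00791). miR2916 passed as lower with DESeq2 (adjusted p = 0.00351) or with no filter in edgeR (0.00110), and miR-105 as higher with DESeq2 (0.0400) or no filter (7.33e-12).

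The soybean libraries differed from each other in names of animal miRNAs. The hyphenated names of common animal families, among them let-7, miR-21, miR-143, miR-148a and miR-26, took 9.75% of the counts of soybean 1 (95% Wilson interval 9.40% to 10.1%) and 24.7% of soybean 2 (24.4% to 25.0%), against 4.63% ± 0.800 in amla, 2.10% ± 0.350 in garlic and 2.23% ± 0.932 in turmeric (SD, n = 2). let-7 had 176 and 1715 counts in the 2 soybean libraries, miR-21, a common animal miRNA, 189 and 2328, and miR-26c 0 and 870. miR-92, miR-486 and miR-191 went the other way, with 368 and 44, 463 and 63, and 202 and 36 counts. Of 24 such names, 16 stood more than 2 times above the median ratio of the plant-style names, which was log2 0.72, and 3 more than 2 times below it. The share of this list moved beside the plant-style share, which was 42.0% in soybean 1 and 36.4% in soybean 2. The list in this form was set after the data were seen. It does not hold all animal names that differed, and families outside it also went both ways. Given after their values were seen, bantam had 18 and 448 counts in soybean 1 and soybean 2, miR-318 24 and 629, and miR-150 237 and 13.

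**Figure D3:**
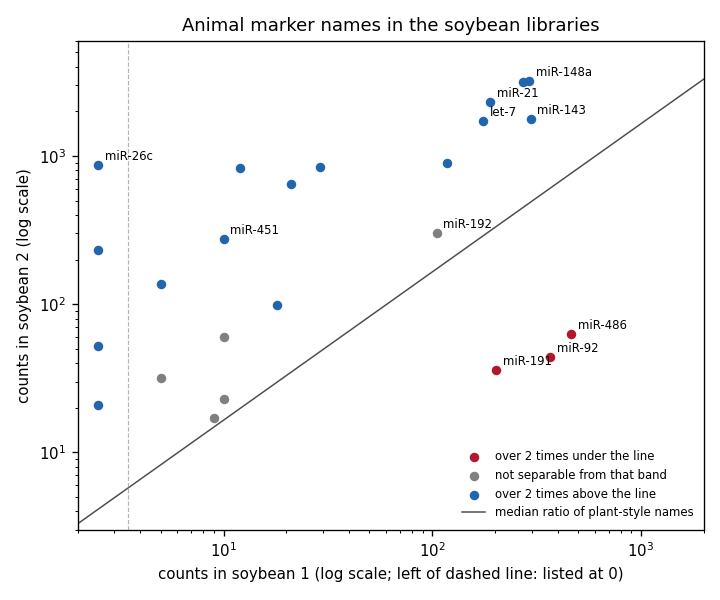
Points give the counts of 24 animal marker names in soybean 1 and soybean 2 (log axes), the line is the median ratio of plant-style names, and points left of the dashed line were listed at 0 in soybean 1. miR-92, miR-486 and miR-191 lie more than 2 times under the line and 16 names lie more than 2 times above it.

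Turmeric vesicles carried more miR-6808, miR-971, miR-93a and miR-8117 than the mean of the other plants on the log scale. They also had a small set of names of their own, led by miR-8432. miR-6808, with 66008 and 73538 counts, was 35.0-fold higher than the mean of the other plants (log2 5.13 ± 0.50 SE, edgeR adjusted p = 0.00739, n = 2 turmeric and 6 other libraries). miR-971 (5215 and 3588 counts) was at least 80.2-fold higher, miR-93a at least 35.9-fold, and miR-8117 26-fold (log2 4.70 ± 0.58, edgeR adjusted p = 0.00778). miR-93a took a larger mean share of counts in amla (1.27%) than in turmeric (0.941%). Its fold rests on garlic and soybean, both at 0. miR-8432, with 134 and 275 counts and 0 in the other plants, was at least 37.7-fold higher. edgeR called 52 names higher and 1 lower, and 3 of the 52 were at 0 in all other libraries. miR-2285bk (524 and 237 counts) was at least 55.8-fold higher, miR-6518 29.5-fold, miR-991 29.3-fold, miR-7069 24.0-fold, miR-5404 15.6-fold, the plant-style miR9559 11.4-fold, miR-10282 10.7-fold, miR-1299 6.02-fold and miR-997 3.34-fold, all as lower bounds. Of these, miR-6518, miR-991, miR-5404, miR9559 and miR-10282 were counted in amla too and were at 0 in garlic and soybean. Against amla alone, edgeR called 0 of the 316 names. The lower name was miR3630 (log2 -3.89 ± 0.63, 15.1-fold, edgeR adjusted p = 0.00937), which had 10 and 11 counts in turmeric and 4809 and 6830 in garlic and is given after its values were seen. miR156 (log2 1.52 ± 0.46, edgeR adjusted p = 0.0876), miR159 (log2 -0.75 ± 0.49), miR2916 (log2 -0.49 ± 0.48), miR-10565 (edgeR adjusted p = 0.0897) and miR-5365 (edgeR adjusted p = 0.199) did not pass. DESeq2 called 46 higher and 8 lower, with an adjusted p of 0.215 for miR-1299 and none given for miR-997, and with total-count scaling miR-2285bk did not pass (edgeR adjusted p = 0.0632). edgeR called 32 higher without turmeric 2, and 3 lower without amla 2, 2 without soybean 1 or soybean 2 and 0 without turmeric 1 (3 lower at an unadjusted p under 0.05). The call of miR3630 was lost without turmeric 1 (edgeR adjusted p = 0.135) or turmeric 2 (0.160). miR-8432, miR-2285bk, miR-1299 and miR-997 lost their calls without turmeric 1 (edgeR adjusted p of 0.0718 to 0.274) or turmeric 2 (0.0952 to 0.160). miR-2285bk and miR9559 were lost without amla 1 (0.0592 and 0.0549), these with miR-991 and miR-5404 without amla 2 (0.0508 to 0.0779), and miR-2285bk without soybean 1 (0.0627) or soybean 2 (0.0749). miR156 passed without amla 2 (0.0387) or soybean 1 (0.0131), and miR156, miR-5365 and miR-10565 passed without garlic 1 (0.0123 to 0.0325) or garlic 2 (0.00776 to 0.0269). With no filter all 3 passed as higher (edgeR adjusted p = 0.000822, 1.14e-16 and 4.97e-18), with plant-style scaling miR156 (0.0122) and miR-10565 (0.0396), and with DESeq2 miR-5365 (adjusted p = 0.000180) and miR156 (0.04997). The no-filter values came from the same libraries with the spread shared over 896 names. They do not measure how far libraries differ, since miR-10565 had 127 and 1322 counts in turmeric and miR-5365 had 0 and 430 in garlic. miR159 passed as lower with total-count scaling (edgeR adjusted p = 0.0123).

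Compared pair by pair, amla and turmeric vesicles had the fewest called miRNAs, while all other pairs differed in many. Between amla and turmeric edgeR called 0 of the 316 names, with 32 at an unadjusted p under 0.05. Without the filter on low counts it called 13 names higher in amla and 21 higher in turmeric. DESeq2 called 4 of the 316 names, which were miR6478, miR-7069, miR-6972 and miR12147, named after their values were seen. The amla minus turmeric difference was log2 -0.96 ± 0.66 for miR-6808, log2 0.04 ± 0.61 for miR156, log2 0.19 ± 0.57 for miR159 and log2 -2.16 ± 0.91 for miR-971 (SE, n = 2 and 2), and the last passed without the filter (edgeR adjusted p = 0.00570). Between amla and garlic, 56 names were higher in amla, among them miR-93a (at least 170-fold), and 109 were higher in garlic. The latter included miR-8546 (at least 2557-fold) and miR166 (at least 508-fold, edgeR adjusted p = 0.0157). Garlic and turmeric differed in 153 names, 106 higher in garlic and 47 in turmeric. miR166 was higher in garlic (log2 7.67 ± 1.79, edgeR adjusted p = 0.0159), and miR-10315b, at 214 and 309 counts in turmeric and 0 in garlic, was at least 54.4-fold lower. miR156 was lower in garlic than in turmeric (log2 -2.59 ± 0.64, edgeR adjusted p = 0.0174) and higher in amla than in garlic (log2 2.63 ± 0.64, edgeR adjusted p = 0.0172). Garlic and soybean differed in 140 names, 117 higher in garlic, among them miR396 (log2 4.71 ± 1.17, edgeR adjusted p = 0.0208), and 23 in soybean, among them miR2118. Amla and soybean differed in 84 names, 24 of them higher in soybean and 60 in amla, among them miR-10565 (at least 600-fold) and miR-971 (at least 211-fold). Soybean and turmeric differed in 76 names, 20 of them higher in soybean. miR159 was called in no pair by edgeR, but with total-count scaling it was higher in soybean than in amla (edgeR adjusted p = 0.0119), garlic (0.0200) and turmeric (0.00745) and higher in garlic than in turmeric (0.0295). Several of these counts changed when 1 library was left out. The names higher in amla and higher in garlic numbered 0 and 0 without amla 1 (58 and 111 at an unadjusted p under 0.05, and 41 and 23 by DESeq2 on all libraries), 4 and 4 without garlic 1, and 15 and 9 without garlic 2. Those higher in amla than in soybean numbered 0 without amla 1 (65 at an unadjusted p under 0.05, and 48 by DESeq2 on all libraries), 40 without amla 2 and 24 without soybean 2. The 24 names higher in soybean than in amla fell in every such edgeR fit, to 0 without amla 1 (26 at an unadjusted p under 0.05, and 13 by DESeq2 on all libraries), 4 without amla 2, 7 without garlic 1 or garlic 2, 5 without soybean 1, 1 without soybean 2 and 8 without turmeric 1 or turmeric 2. Those higher in garlic than in soybean numbered 20 without garlic 1, 13 without garlic 2 and 21 without soybean 2. Those higher in soybean than in garlic numbered 3 without garlic 1, 0 without garlic 2 (21 at an unadjusted p under 0.05, and 23 by DESeq2 on all libraries), 8 without soybean 1, 3 without soybean 2, 11 without turmeric 1 and 12 without turmeric 2. For garlic and turmeric, 1 name was higher in garlic and 0 in turmeric without garlic 1 (98 and 49 at an unadjusted p under 0.05, and 22 and 41 by DESeq2 on all libraries), and 2 and 7 without garlic 2. The 20 names higher in soybean than in turmeric fell to 8 without garlic 1 or garlic 2, 2 without soybean 1 or turmeric 1, and 1 without soybean 2 or turmeric 2, and those higher in turmeric fell to 18 without soybean 2. Of the names given for pairs, miR156 lost its calls for garlic against amla and against turmeric without garlic 1 (edgeR adjusted p = 0.0965 and 0.0854), garlic 2 (0.0857 and 0.0759), turmeric 1 (0.0627 and 0.152) or turmeric 2 (0.0642 and 0.0837), and against amla without amla 1 (0.0597). miR166 lost the same 2 calls without garlic 1 (0.0620 and 0.0786) or garlic 2 (0.0636 and 0.0792), against amla without amla 1 (0.0547) and against turmeric without turmeric 1 (0.105) or turmeric 2 (0.121). miR-93a and miR-8546 were lost without amla 1 (0.0547 for both), miR-8546 (0.0513) and miR-10315b (0.0508) without garlic 1, miR396 without garlic 2 (0.0594), turmeric 1 (0.0750) or turmeric 2 (0.0749), and miR2118 without garlic 2 (0.0508) or soybean 2 (0.0584). Between amla and soybean, miR-971 was lost without amla 1 (0.0560), and miR-10565 without any 1 of the amla, soybean or turmeric libraries (0.0652 to 0.128) and with total-count scaling (0.0641).

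Among conserved plant families that regulate development, garlic vesicles carried more miR166, miR171 and miR396, with miR394 also called higher at low counts, and soybean vesicles lacked counts of miR164. In sums over family members, miR171, which targets GRAS transcription factors, had 123 and 173 counts in garlic, miR394, which targets the F-box gene LCR, 12 and 17, and both were at 0 in the other plants (edgeR adjusted p = 0.00601, n = 2 and 6). The miR394 counts lay near the lowest listed count of 5, so that a 0 in a small library does not show a lower share. The miR396 sum was higher in garlic (log2 2.78 ± 0.84, edgeR adjusted p = 0.0408). With the replicate number as a block, miR394 and miR396 did not pass in garlic (edgeR adjusted p = 0.282 and 0.0765). miR164, which targets NAC transcription factors, had 57 and 28 counts in amla, 57 and 116 in garlic, 53 and 57 in turmeric and 0 in both soybean libraries. It was called lower in soybean (edgeR adjusted p = 0.0199). It was also called higher in each of amla, garlic and turmeric, where the mean of the other plants on the log scale included soybean at 0. The miR156, miR159 and miR167 sums were called in no plant. With total-count scaling miR159 and miR167 passed in soybean (edgeR adjusted p = 0.00652 and 0.0140) and turmeric (0.0119 and 0.0246) and miR156 in amla (0.00892) and garlic (0.00644), miR159 and miR167 as higher in soybean and lower in turmeric and miR156 as higher in amla and lower in garlic. The miR156 sum also passed without 1 library, in amla without soybean 1 or soybean 2 (0.0135 and 0.0499), in garlic without amla 1, soybean 1 or soybean 2 (0.0122 to 0.0234), in soybean without amla 1 (0.0339) and in turmeric without amla 1, garlic 1, garlic 2 or soybean 1 (0.0129 to 0.0393). DESeq2 called the miR156 sum lower in garlic (adjusted p = 0.00793) and higher in turmeric (0.0493). It also called the miR396 sum lower in soybean (DESeq2 adjusted p = 0.00150) and the miR166 sum lower in amla (1.76e-05) and turmeric (0.0241). In garlic miR159 passed without amla 1 (0.0462) and miR167 without amla 1 or soybean 1 (0.0176 and 0.0116). The list of development regulators took 10.4% ± 0.198 of counts in amla, 15.1% ± 0.889 in garlic, 23.1% ± 4.42 in soybean and 6.12% ± 1.40 in turmeric (SD, n = 2). Of its 8 tested names, 5 were higher and 1 lower in garlic, also when adjusted over the list alone. In the other plants 1 was higher in amla (2 higher and 1 lower adjusted over the list alone), 1 higher and 1 lower in soybean (1 and 2 adjusted over the list alone), and 1 higher in turmeric (1 adjusted over the list alone). The list was not called against the other names in any plant by limma camera (adjusted p = 0.580 in garlic). limma fry, which asks whether its members moved 1 way on balance, gave an adjusted p of 0.0356 in garlic for this list. Its members miR171 and miR394 passed the filter on low counts through garlic alone, so this fry result gives no separate support for a garlic excess. For the lists described next fry gave 0.0156 for legume and 0.0270 for defence names in soybean and 0.000625 for let-7 names in amla, and it does not compare a list with other names.

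The legume families miR1509 (51 and 214 counts) and miR3522 (115 and 193) were called higher in soybean as sums (edgeR adjusted p = 0.0350 and 0.0453, n = 2 and 6), while miR1510, miR1511 and miR1507 (42 and 39 counts) did not pass (0.0545, 0.0581 and 0.0757). The first of these had 0 counts in the other plants and 0.30% ± 0.131 of counts in soybean, and miR1511 0.388% ± 0.0919 (SD, n = 2). miR1510 passed without amla 1 (0.0402), and with total-count scaling miR1510, miR1511 and miR1507 passed (0.0188, 0.0461 and 0.0372), while with DESeq2 miR1511 passed (0.0339) and miR1509 did not (0.0701). The sum of miR2118, a defence family with 5 counts in each garlic library, also passed (edgeR adjusted p = 0.0199). The legume list took 1.40% ± 0.334 of counts in soybean, 0.0198% ± 0.00171 in garlic (SD, n = 2) and 0 counts in amla and turmeric. It was the 1 call among 16 combinations of 4 lists and 4 plants by limma camera (adjusted p = 0.00529), with 2 of 3 tested names higher and 3 adjusted over the list alone. The call did not hold with an estimated correlation (adjusted p = 0.873). The 3 tested names, miR1507, miR1511 and miR3522, passed the filter on low counts through soybean alone. Legume names could thus enter the test only where high in soybean, so the camera and fry results give no separate support for a legume excess. The defence list took 6.72% ± 2.93 of counts in soybean and 0.113% to 0.157% elsewhere. It had 2 of 4 names higher in soybean (3 adjusted over the list alone), 1 higher and 1 lower in garlic (the same counts adjusted over the list alone), 0 in amla and 0 in turmeric (1 higher adjusted over the list alone). Its limma camera adjusted p in soybean was 0.0591. The defence names miR1507 and miR2118 passed the filter through soybean alone, so camera and fry give no separate support for a defence excess there. The let-7 list had 3 of 5 names higher in amla (3 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 0.523). It had 0 in the other plants (2 higher in soybean adjusted over the list alone). The 2 lower in amla and the 2 higher in soybean are let-7 and Let-7, 2 spellings with the same counts, and limma camera and fry counted both. The names let-7f, let-7g and let-7i, at 0 outside amla, passed the filter through amla alone, so fry gives no separate support there. In soybean the camera direction of let-7 was up while the median and mean of its fitted changes were below 0, and the let-7 sum, not called there, passed as higher with total-count scaling (edgeR adjusted p = 0.0233) or DESeq2 (adjusted p = 0.0416). The wider animal list with hyphens, set after the data were seen, was lower in garlic by limma camera (adjusted p = 0.000895), with a median of log2 -0.58 against log2 1.39 for the other tested names. This did not hold with an estimated correlation (adjusted p = 0.480). In turmeric the camera direction was also down (adjusted p = 0.0496, and adjusted p = 0.551 with an estimated correlation), but the median of the list, log2 -0.12, lay above that of the other names, log2 -1.60, so that test and median differed in direction. In soybean the direction was up and the list did not pass (adjusted p = 0.429, and adjusted p = 0.667 with an estimated correlation), but it passed with total-count scaling (adjusted p = 0.0179). In amla the median of this list was below 0 and its mean above 0, with a camera direction of down.

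The remaining plant families were sparse. miR168, which targets AGO1, was higher in garlic as a sum (344 and 493 counts, edgeR adjusted p = 0.00619), and miR162 was lower in garlic, at 0, and counted in amla (61 and 32), soybean (52 and 85) and turmeric (111 and 87). It was called higher in turmeric (edgeR adjusted p = 0.0287), where the mean of the others included garlic at 0, and not in amla (0.0742) or soybean (0.107). It passed as higher in amla with total-count scaling (0.0113) or without soybean 1 (0.0224) or soybean 2 (0.0499), and in soybean with total-count scaling (0.0131) or DESeq2 (adjusted p = 0.0308). miR528, known mainly from monocots, was counted in amla (29 and 26) and turmeric (54 and 32) and at 0 in garlic and soybean, and was called higher in both (edgeR adjusted p = 0.0108 and 0.0105). miR444, another monocot family, was counted in garlic (63 and 69) and in no other plant (edgeR adjusted p = 0.00601, DESeq2 adjusted p = 0.0526). The lists of small RNA pathway regulators, auxin regulators, nutrient families and monocot families had too few tested names for a test. Their shares in amla, garlic, soybean and turmeric were 0.108%, 0.399%, 0.156% and 0.120% for the small RNA pathway, 0.182%, 0.396%, 0.818% and 0.119% for auxin, 0.0565%, 0.0158%, 0.0111% and 0.0480% for nutrients, and 0.0565%, 0.0645%, 0 and 0.0437% for monocot families (means, n = 2). Over all 296 tested families, edgeR called 50 higher and 5 lower in amla, 42.6% of the families in garlic of which 4 were lower, 15 higher and 10 lower in soybean, and 49 higher and 1 lower in turmeric. Without amla 1 edgeR called 2 families in amla and without amla 2 it called 0 in amla (66 at an unadjusted p under 0.05; 47 by DESeq2 on all libraries) and 0 in soybean (63 and 73). In garlic it called 2 without garlic 1 or garlic 2, in soybean 7 without garlic 1 or soybean 2, 2 without garlic 2, 6 without turmeric 1 and 5 without turmeric 2, and in turmeric 33 without turmeric 2. The garlic families named here lost their calls without garlic 1 (edgeR adjusted p of 0.0674 to 0.130) or garlic 2 (0.0725 to 0.174), and miR396 also without amla 2 (0.0976), turmeric 1 (0.116) or turmeric 2 (0.118). In amla miR164 and miR528 were lost without amla 1 (0.0834 and 0.0844) or amla 2 (0.0666 and 0.0640), and miR164 without garlic 1 (0.0877), garlic 2 (0.0794) or soybean 2 (0.0558). In soybean miR2118 was lost without amla 2, garlic 2, turmeric 1 or turmeric 2 (0.0516 to 0.0559), miR164 without these (0.0516 to 0.0657), garlic 1 (0.0593) or soybean 2 (0.0714), and miR1509 and miR3522 without any 1 library other than amla 1 (0.0522 to 0.152). In turmeric miR164 was lost without amla 2, garlic 1, garlic 2, soybean 2, turmeric 1 or turmeric 2 (0.0515 to 0.0750) and miR162 without amla 2 (0.0774), turmeric 1 (0.150) or turmeric 2 (0.0979).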

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

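Of the alternatives given here, scaling on plant-style names was chosen after the data were seen, as were the tests on the wider animal list. Of 82 named results, 66 passed, and none of these reversed under any alternative given here. Many were chosen because both libraries of the plant lay above or below all others, often with counts of 0. A reversal was then hardly possible, so its absence gives no separate support. Named calls lost were 13 with DESeq2, 21 with the replicate block, 4 with total-count scaling, 2 with plant-style scaling, 1 without the filter, 0 with DESeq2 size factors or merged names, and 10 to 24 without 1 library, where a lone library is assumed to vary like the other groups. In the order higher and lower, the unaltered counts were 58 and 4 in amla, 5 lower of 129 in garlic, 25 and 11 in soybean, and 52 and 1 in turmeric. The DESeq2 Wald test called 37 and 13 in amla, 59 and 39 in garlic, 50 lower in soybean and 8 lower in turmeric; it called 23 names higher in garlic than in amla, 13 in soybean than in amla, 1 in amla and 3 in turmeric between these, 43 in garlic than in soybean, 22 in garlic than in turmeric, and 73 soybean families. It shared 40 of 62 edgeR calls in amla, 63 of 129 in garlic, 25 of 36 in soybean and 44 of 53 in turmeric, and the share of higher calls went from 93.5% to 74.0% in amla, 96.1% to 60.2% in garlic, 69.4% to 33.3% in soybean and 98.1% to 85.2% in turmeric. Without the filter, where more names were tested, the calls were 89 and 11 in amla, 220 and 16 in garlic, 62 and 26 in soybean, 96 and 8 in turmeric; between pairs they were 48 higher in soybean than in amla, 13 in amla and 21 in turmeric between these, 50 in soybean than in garlic, 82 in turmeric than in garlic, 49 in soybean than in turmeric and 107 in turmeric than in soybean. Total-count scaling gave 43 higher in soybean (79.6% of calls), 4 lower in turmeric, 36 higher in soybean than in garlic, 33 in soybean than in turmeric, and 52 soybean families; DESeq2 size factors gave 2 lower in turmeric; plant-style scaling gave 2 lower in amla, 8 lower in garlic, 2 lower in turmeric and 35 higher in soybean than in garlic. The median change of all tested names shifted by 0.19, -0.57, 0.23 and -0.44 (log2; amla, garlic, soybean, turmeric) with total-count scaling, by 0.32, -0.98, 0.32 and 0.31 with plant-style scaling, and by -0.12 in garlic with DESeq2 size factors. Named results that passed only under an alternative numbered 5 with DESeq2, 8 without the filter and 3 each with total-count and plant-style scaling, among them miR159, higher in soybean (edgeR adjusted p = 0.00791) and lower in turmeric (0.0123) with total-count scaling, and miR156, higher in amla with total-count (0.00931) or plant-style scaling (0.00938). Of the family sums of the lists, DESeq2 added 13 calls and ended 2, total-count scaling added 13, and the block ended 11. With the replicate block edgeR called 14 and 1 in amla, 57 and 3 in garlic, 7 higher in soybean, 24 higher in turmeric, 13 and 21 for amla and garlic (higher in the first and in the second plant), 16 and 3 for amla and soybean, 20 and 5 for garlic and soybean, 20 and 17 for garlic and turmeric, 0 and 11 for soybean and turmeric (16 names higher in soybean at an unadjusted p under 0.05), and 15, 59, 3 and 22 families in amla, garlic, soybean and turmeric; libraries of the same number share only a number, since the correlations of their deviations from the plant means ran from -0.333 to 0.178. Without 1 library in turn, the calls ranged from 0 to 65 higher and 0 to 6 lower in amla, 38 to 127 and 2 to 9 in garlic, 0 to 11 and 3 to 14 in soybean, and 32 to 57 and 0 to 3 in turmeric, all by edgeR. The same ranges were 0 to 64 and 0 to 118 for amla and garlic (higher in the first and in the second plant), 0 to 68 and 0 to 8 for amla and soybean, 13 to 120 and 0 to 23 for garlic and soybean, 1 to 110 and 0 to 52 for garlic and turmeric, 1 to 20 and 18 to 62 for soybean and turmeric, and 0 to 65, 2 to 131, 0 to 28 and 33 to 56 families in amla, garlic, soybean and turmeric. At the counts of 0, 65 higher and 6 to 7 lower names passed an unadjusted p under 0.05 in amla, 34 higher in soybean, 3 lower in turmeric, 65 and 26 for amla and soybean, 21 higher in soybean than in garlic and 49 higher in turmeric than in garlic. For lists, an estimated correlation left 0 calls (0 at an unadjusted p under 0.05) and fry made 4; for the wider animal list the block gave an adjusted p of 0.0345 in soybean (up), 0.0222 in garlic (down) and 0.338 in turmeric (up). Detection at 50 counts gave 37 names in amla, 86 in garlic, 30 in soybean, 44 in turmeric and 12 in all plants. Thinning gave 93 in garlic, 50 in turmeric and 14 in all plants. Fewer detected names follow by construction from the higher limit in the first case and from fewer counts in the second. For the other changes the cause was not tested. The authors' normalized values, being the counts times 1 factor per library, leave shares as they are by construction.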

Other observations

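Every test of a pattern given in this part was chosen after the results were seen.

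Names shared by amla and turmeric went beyond miR-6808. Both carried miR-93a, miR-6518 (477 and 875 counts in turmeric), miR-6599 (656 and 567 in amla, 185 and 238 in turmeric) and miR-10315b (152 and 175, 214 and 309), none of which had a count in garlic or soybean. Some names were absent from soybean alone, such as the poplar entry miR6478 (400 and 479 counts in garlic, 24 and 26 in turmeric), which was also counted in amla.

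Several families were counted under different names in the 2 libraries of a plant. In soybean, miR1509 had 51 counts as miR1509a in replicate 1 and 214 as miR1509 in replicate 2, and miR1510 had 106 counts as miR1510 in replicate 1 and its remaining counts as miR1510b in replicate 2. In garlic, miR475 had 39 and 144 counts as miR475c and miR475d in replicate 1 and 278 as miR475 in replicate 2, and in turmeric 23 counts as miR-99b faced 57 as miR-99. Of 280 name calls against the other plants, 250 had a family sum called the same way.

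The first pattern is the resemblance of amla and turmeric. Carry-over of turmeric reads into amla as its source would bring every abundant turmeric family along, but 8 of 58 turmeric family sums with at least 100 counts stood in amla at under 0.1 of the miR-6808 ratio. Carry-over the other way is opposed by 5 of 42 amla sums, among them miR-330 with 651 counts in amla and 69 in turmeric, where the ratio predicts 1658; a smaller carry-over either way is not excluded. Nor did miR-6808 alone set the resemblance: without it the lowest amla to turmeric r across names was 0.664, against a highest r of 0.307 between any other plants. A shared sequence in both plants that matches an animal entry, a shared outside source and a real likeness of the vesicles may each remain, and no sequence was at hand to tell them apart. The titles number the turmeric libraries 14 and 15 and the amla libraries 16 and 17. miR528, known mainly from monocots, was counted in amla (29 and 26) as well as in turmeric (54 and 32). Neither observation decides between these explanations.

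The second pattern is the excess of animal names in soybean 2. A difference in depth alone would leave every ratio of replicate 2 to replicate 1 at 1 value, but 15 of 19 animal family sums lay more than 2 times from the median of the plant-style sums, 12 above and 3 below it; of the plant-style sums 6 of 22 lay as far away. A single animal source added to replicate 2 does not account for 3 names, miR-92, miR-486 and miR-191, which stood more than 2 times lower there. These 3 lie outside the excess, so they cannot decide whether 1 source gave the 12 sums above the median. From replicate 1 to replicate 2 their shares of counts also rose in amla and turmeric, and they moved both ways in garlic. An outside source of animal RNA, 1 or more, is a candidate explanation that was not tested. The titles number soybean 1 as 1 and the other libraries as 11 to 17, and the labels name no batch, so a difference of library batch stays open too.

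The third pattern is miR3630 outside garlic. It had 4809 and 6830 counts in garlic and 10 to 36 in each other library, which add up to 1.10% of its garlic counts. Carry-over from garlic at the rate of the highest of these libraries would give 9.15 counts or more, enough to be listed there with a Poisson probability of 95%, to 9 other abundant garlic names. Of these 9 names, 4 were at 0 in all 6 other libraries with all names of their family, among them miR-8546, for which 109 counts were predicted, and miR-277, for which 29.2 were predicted. Low levels of miR3630 in the other plants, or reads of a related sequence counted under that name, could account for its counts and were not tested.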
